A study of Mus musculus with 14 samples.

How the data were processed

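Liver total RNA of 14 mice had been labelled with biotin and put on Affymetrix mouse arrays of 12488 probe sets, 1 mouse per array. Values are the signal intensity of each probe set as deposited by the authors, made with MAS5 per the submitters' processing notes, on a linear scale. No detection calls were used. The trimmed mean of the arrays (2% trimmed at each end) ran from 500.357 to 500.437, so the values were used as deposited. No value was missing, and correlations of array pairs on the log2 scale ran from 0.812 to 0.964.

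Groups were taken from the labels: wild type 6 months (animals 82, 84, 86 and 88), dwarf 6 months (83, 85, 87 and 89), wild type 22 months (1, 2 and 24) and dwarf 22 months (3, 4 and 8). Values below the pooled 25th percentile of 54.9 were set to it, and a probe set was tested when it exceeded the pooled median of 184.8 on at least 3 arrays. After 66 control probe sets were left out, 7227 probe sets were tested. A fold against a group with all arrays at the floor is given as a lower bound. Of the 12488 probe sets, 10855 had 1 gene symbol in the array annotation, 396 had several and 1237 were not listed (6471, 262 and 494 of those tested). For 10839 of the 10855 the gene identifier was in the mouse reference annotation, which was used for names and chromosomes alone. A gene with several tested probe sets was represented by the one with the highest mean, which left 5473 genes.

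A linear model with 1 mean per group was fitted to the log2 signal of all 14 arrays with limma 3.58.1 in R 4.3.3 (eBayes with an intensity trend). Its 6 contrasts were dwarf against wild type at each age, 22 against 6 months in each genotype, the interaction and the genotype difference averaged over ages. P values were adjusted by Benjamini-Hochberg within each contrast, and a probe set passed at an adjusted p under 0.05. Of 60 gene lists, 57 had at least 3 tested genes and were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry (directional and mixed) served as alternatives. With an estimated correlation, 1 of 20 lists passed at 6 months, 13 of 29 at 22 months, 0 of 20 with age in wild type mice, 0 of 9 with age in dwarf mice, 1 of 22 for the interaction and 10 of 24 for the average. Many lists share members: 7 of 9 male-biased genes stand in another list.

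Named genes followed a rule: the 8 largest changes in each direction at 6 and at 22 months, and the 6 largest in each direction for the ageing and interaction contrasts, among genes that passed and, except for the interaction, whose values did not overlap between the groups; the up to 4 members with the smallest p of each list that passed; and a fixed set of genes of endocrine and lipid regulation. Of that set, Mup1 and Pou1f1 had no probe set of 1 gene, and some members are not reported here. Probe sets with no or several symbols were not named. Measures of the arrays (3' to 5' ratios of the Gapdh and beta-actin controls, the 18S control and the 25th percentile) were compared with exact two-sided permutation tests, adjusted over 20 tests. With 3 against 3 arrays such a test cannot go below 0.1.

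Groups, tests, lists, the rule for named genes and most alternatives were fixed before the data were examined. These alternatives were quantile and median scaling, other floors, a pseudocount, other filters, other variance models, array weights, fits of the compared groups alone and leaving out each array. The fits with the 18S signal or with the mean log2 3' to 5' ratio as a covariate were chosen after seeing the data. A fit with a batch term drawn by eye from the control transcripts was also run and seen. It left few age calls and reversed Map3k12 with age in dwarf mice, and it was dropped because the labels give no such batch and the term nearly followed age.

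The pipeline was run on simulated changes (66 or 67 probe sets per fold and contrast). Of probe sets changed 1.5-, 2- and 4-fold it recovered 22.4%, 58.2% and 92.4% at 6 months, 7.46%, 50.7% and 78.8% at 22 months, 16.4%, 40.3% and 92.4% with age in wild type mice, 25.4%, 59.7% and 90.9% with age in dwarf mice, 5.97%, 29.9% and 72.7% for the interaction, and 38.8%, 68.7% and 100% for the average, with 1 to 8 false calls per contrast. Camera called 10 of 10 lists of 15 genes shifted by log2 0.5 and 0 of 10 unshifted ones. False calls among correlated genes were not tested.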

Results

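Affymetrix arrays measured liver RNA of Snell dwarf mice, which carry a mutation of Pit-1 (Pou1f1), the transcription factor needed for the pituitary cells that make growth hormone, prolactin and thyrotropin, and of wild type control mice. Each of the 14 arrays held the RNA of 1 mouse: 4 wild type and 4 dwarf mice of 6 months, and 3 wild type and 3 dwarf mice of 22 months. The labels give a separate animal number for each array and no sex, strain or batch. Values are MAS5 signals, which the authors scaled to a 2% trimmed mean near 500. The median signal per array ran from 166.8 to 221.05, and 19.5% to 27.9% of the 12488 probe sets lay at or below the floor of 54.9 that was used in place of a detection call. The number of arrays limits the precision.

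In a principal component analysis of the 7227 tested probe sets, component 1 held 31.7% of the variance and component 2 held 16.1%. Dwarf mice of 6 months had component 1 scores of 35.8 ± 9.04 (SD, n = 4), against -10.4 ± 7.97 (n = 4) in wild type mice of 6 months, -27.7 ± 2.73 (n = 3) in wild type mice of 22 months and -6.16 ± 1.91 (n = 3) in dwarf mice of 22 months. The 6-month wild type animal 88 scored -21.3 on component 1 and -4.57 on component 2, next to the 22-month wild type arrays. The ratio of 3' to 5' signal of beta-actin, a measure of RNA integrity and labelling, was 1.87 ± 0.602 in wild type and 2.51 ± 0.209 in dwarf mice of 6 months, and 1.61 ± 0.118 and 1.46 ± 0.18 at 22 months. The signal of the 18S ribosomal RNA control was 339.8 or more on each 22-month array, 587.6 for animal 88 and 60.8 to 217.4 on the other 6-month arrays.

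**Figure D1:**
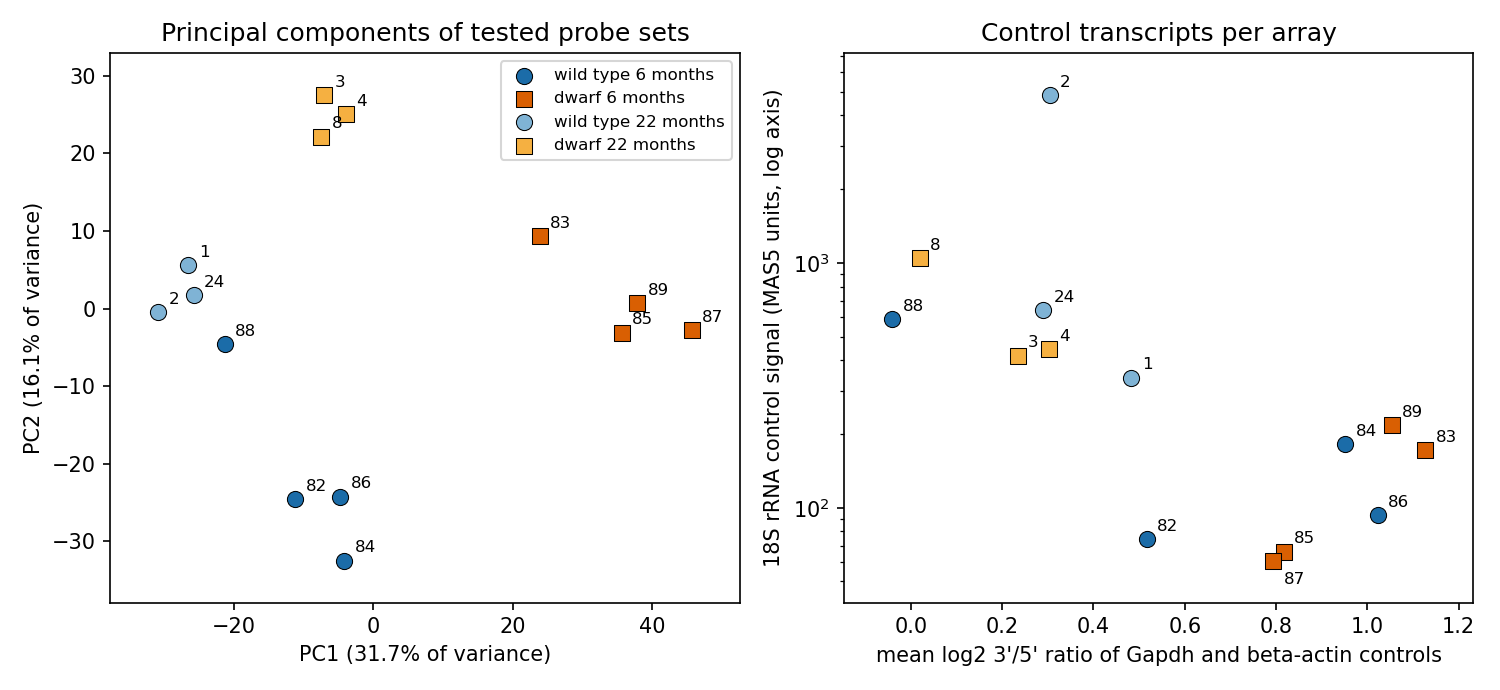
Left, scores of the 14 arrays on the first and second principal components of the tested probe sets (unitless); right, the 18S ribosomal RNA control signal (MAS5 units, log axis) against the mean log2 ratio of 3' to 5' signal of the Gapdh and beta-actin controls, with animal numbers beside the points. Animal 88, of 6 months, lies with the 22-month arrays in the right panel, with an 18S signal of 587.6.

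The comparison of dwarf with wild type mice at 6 months asked how the loss of Pit-1 changes the liver of young adults. Of the growth hormone axis, Igfals and Igf1 were lower in dwarf mice (n = 4 and 4): Igfals, which encodes the acid-labile subunit that carries IGF-1 in blood, was 36.6-fold lower (89.9 ± 28.3 against 3182 ± 302, mean signal ± SD), and Igf1 itself was 3.48-fold lower (1283 ± 222 against 4435 ± 523). The list of that axis did not pass (3 of 14 higher and 4 lower, 4 higher and 5 lower adjusted over the list alone, adjusted p = 0.0619, or adjusted p = 0.173 with an estimated correlation). The steroid dehydrogenase Hsd3b5 was 64.4-fold lower and the cytochrome P450 Cyp2b13 was 23.6-fold higher. Thrsp, a thyroid hormone-induced regulator of fat synthesis, was 26-fold lower (389.8 ± 204 against 9542 ± 2814). In all, 460 probe sets were higher and 502 lower, 962 of the 7227 tested (13.3%), and 167 of the higher and 212 of the lower ones differed by at least 2-fold.

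The largest decreases were in Wfdc21, which encodes a secreted whey acidic protein-domain protein (145-fold, 118 ± 52.7 against 16226 ± 2730.0), Hsd3b5, Serpina12 (at least 40.3-fold, since all 4 dwarf arrays lay at the floor), Igfals, the acute phase protein Orm1 (27.8-fold), Thrsp, the growth factor receptor Egfr (22.3-fold) and the serum amyloid Saa2 (15.4-fold). The largest increases were in Igfbp1, an insulin-suppressed IGF binding protein (33.6-fold, 9913 ± 5313 against 267 ± 76.4), Cyp2b13, Pcp4l1 (20.2-fold), lipoprotein lipase Lpl (14.7-fold), the interleukin-1 receptor antagonist Il1rn (14.5-fold), the sulfotransferase Sult2a2 (13.3-fold), the guanylate cyclase Gucy2c (8.51-fold) and the MHC class II chain H2-Aa (7.88-fold). For these 16 genes the adjusted p was 0.00251 or lower. The probe sets of Igfbp1 and Saa2 have a suffix that Affymetrix gives to sets which may also detect related transcripts. Below, single values with ± are log2 fold changes with the standard error from limma, and mean signals have SD.

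Male-biased liver genes were lower as a list (adjusted p = 1.27e-11, or adjusted p = 0.00663 with an estimated correlation). Of 9 measured, 7 were lower and 2 did not pass (7 lower adjusted over the list alone). They included -2.03 ± 0.16 for Mup3, a major urinary protein, -4.48 ± 0.22 for Egfr and -6.01 ± 0.34 for Hsd3b5. Female-biased liver genes were higher as a list (adjusted p = 4.85e-08, or adjusted p = 0.062 with an estimated correlation). Of 9 measured, 7 were higher and 2 did not pass (7 higher adjusted over the list alone). Examples were 2.83 ± 0.38 for Hao2, a peroxisomal hydroxyacid oxidase, 2.80 ± 0.22 for Cyp4a14, a fatty acid omega-hydroxylase, and 3.74 ± 0.41 for Sult2a2. Thyroid hormone responsive genes were lower as a list (adjusted p = 0.00034, or adjusted p = 0.062 with an estimated correlation). Of 13 measured, 6 were lower and 7 did not pass (6 lower adjusted over the list alone). Changes were -3.48 ± 0.32 for Me1, malic enzyme, -2.41 ± 0.31 for Dio1, the type 1 deiodinase (3 of 4 dwarf arrays at the floor), and -2.49 ± 0.41 for Fasn, fatty acid synthase. Genes regulated by the xenobiotic receptors CAR and PXR were higher as a list (adjusted p = 0.000137, or adjusted p = 0.0554 with an estimated correlation). Of 16 measured, 10 were higher, 2 were lower and 4 did not pass (12 higher and 2 lower adjusted over the list alone). Higher members included 4.56 ± 0.35 for Cyp2b13, 0.80 ± 0.12 for Gstm1 and 0.80 ± 0.14 for Gstm3, and Aldh1a7 was lower (-1.29 ± 0.21). Cytochrome P450 2 family genes were higher as a list (adjusted p = 0.0327, or adjusted p = 0.158 with an estimated correlation). Of 13 measured, 8 were higher, 3 were lower and 2 did not pass (8 higher and 3 lower adjusted over the list alone). Cyp2c39 was higher (1.63 ± 0.17) and Cyp2f2 lower (-2.70 ± 0.23).

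Fatty acid synthesis genes were lower as a list (adjusted p = 6.36e-10, or adjusted p = 0.101 with an estimated correlation). Of 13 measured, 10 were lower and 3 did not pass (11 lower adjusted over the list alone). Besides Thrsp and Me1, log2 changes were -1.99 ± 0.21 for Elovl5, a fatty acid elongase, and -1.45 ± 0.23 for Srebf1, the transcription factor that drives these genes. Cholesterol synthesis genes were lower as a list (adjusted p = 3.72e-05, or adjusted p = 0.101 with an estimated correlation). Of 17 measured, 8 were lower and 9 did not pass (1 higher and 10 lower adjusted over the list alone). Examples were -1.99 ± 0.28 for Idi1, isopentenyl diphosphate isomerase, -1.61 ± 0.26 for Sqle, squalene epoxidase, -1.39 ± 0.25 for Msmo1 and -1.27 ± 0.21 for Hmgcs1. Bile acid synthesis and transport genes were lower as a list (adjusted p = 0.00102, or adjusted p = 0.0773 with an estimated correlation). Of 12 measured, 4 were lower and 8 did not pass (5 lower adjusted over the list alone). These were -1.36 ± 0.25 for Cyp7b1, an oxysterol hydroxylase, -0.82 ± 0.16 for Abcb4, the canalicular phospholipid transporter, -1.16 ± 0.15 for Hsd17b4 and -1.03 ± 0.25 for Hsd3b7, while Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 0.02 ± 0.49 (adjusted p = 0.983). Peroxisomal fatty acid oxidation genes were lower as a list (adjusted p = 0.00491, or adjusted p = 0.183 with an estimated correlation). Of 12 measured, 1 was higher, 4 were lower and 7 did not pass (1 higher and 5 lower adjusted over the list alone). The transporter Abcd3 was lower (-1.41 ± 0.13) and its homologue Abcd2 higher (2.18 ± 0.45).

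Complement genes were lower as a list (adjusted p = 4.26e-05, or adjusted p = 0.0773 with an estimated correlation). Of 17 measured, 8 were lower and 9 did not pass (9 lower adjusted over the list alone). Changes were -2.68 ± 0.18 for C9, -1.59 ± 0.27 for Mbl1, -1.40 ± 0.16 for C8g and -0.94 ± 0.14 for C4bp. Acute phase proteins were lower as a list (adjusted p = 0.0107, or adjusted p = 0.311 with an estimated correlation). Of 21 measured, 8 were lower and 13 did not pass (3 higher and 9 lower adjusted over the list alone). Orm3 (-2.18 ± 0.44) and Apcs (-1.92 ± 0.23) were among them. Interferon-stimulated genes were lower as a list (adjusted p = 0.00473, or adjusted p = 0.247 with an estimated correlation). Of 14 measured, 1 was higher, 5 were lower and 8 did not pass (1 higher and 7 lower adjusted over the list alone). Iigp1 (-1.91 ± 0.41) and Ifi35 (-1.28 ± 0.25) were lower, and Usp18, a negative regulator of interferon signalling, was higher (2.64 ± 0.41). MHC class I and antigen processing genes were lower as a list (adjusted p = 0.00136, or adjusted p = 0.22 with an estimated correlation). Of 13 measured, 1 was lower and 12 did not pass (1 lower adjusted over the list alone). Endoplasmic reticulum chaperones were lower as a list (adjusted p = 0.00392, or adjusted p = 0.062 with an estimated correlation). Of 17 measured, 1 was higher, 8 were lower and 8 did not pass (2 higher and 9 lower adjusted over the list alone). Lower members included -1.19 ± 0.19 for Manf, -1.30 ± 0.30 for Pdia6, -1.09 ± 0.25 for Pdia3 and -0.61 ± 0.14 for Hspa5. Smaller calls were those of the proteasome (5 lower of 28, 5 lower adjusted over the list alone, adjusted p = 0.000448, or adjusted p = 0.194 with an estimated correlation) and iron handling (2 lower of 10, 4 lower adjusted over the list alone, adjusted p = 0.0241, or adjusted p = 0.101 with an estimated correlation), with -1.22 ± 0.19 for Hfe, the haemochromatosis protein.

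MHC class II and antigen-presenting cell genes were higher as a list (adjusted p = 0.0016, or adjusted p = 0.183 with an estimated correlation). Of 9 measured, 3 were higher and 6 did not pass (6 higher adjusted over the list alone). H2-Aa and H2-Eb1 (0.88 ± 0.20) were higher. Endothelial markers were higher as a list (adjusted p = 0.00953, or adjusted p = 0.101 with an estimated correlation). Of 9 measured, 3 were higher and 6 did not pass (7 higher adjusted over the list alone). Stab1 (0.97 ± 0.19) and Ramp2 (0.91 ± 0.20) were higher. Cytosolic ribosomal protein genes were higher as a list (adjusted p = 0.000756, or adjusted p = 0.265 with an estimated correlation). Of 20 measured, 8 were higher and 12 did not pass (12 higher adjusted over the list alone). Rps18 was called (0.63 ± 0.15), and lost the call with median scaling, as did Rpl19, Rps24 and Rps4x. Metallothioneins were higher as a list (adjusted p = 0.0315, or adjusted p = 0.18 with an estimated correlation). Of 3 measured, 1 was higher and 2 did not pass (3 higher adjusted over the list alone). The metal-binding Mt1 was higher (1.89 ± 0.41). Beside these increases, the low end of the signal scale was higher in dwarf mice: the 25th percentile per array was 65.3 ± 7.76 against 52.6 ± 3.01 (SD, n = 4 each, exact two-sided permutation p = 0.0286, the smallest possible, or 0.114 after Benjamini-Hochberg adjustment over 20 tests of array measures). The split into higher and lower depended on the scaling: 47.8% of calls were higher as deposited and 18.2% with each array scaled to a common median (188 higher and 846 lower), which moved the median log2 change of all tested probe sets from 0.10 to -0.10. A fit of the 8 arrays alone called 279 as higher. List calls ended under some settings (highest adjusted p of each list): without dwarf animal 83, 0.0702 for cytochrome P450 2 family; without a filter, 0.128 for metallothioneins; with the filter at the 75th percentile, 0.0901 for acute phase proteins, 0.149 for interferon-stimulated genes, 0.195 for endothelial markers and 0.0937 for iron handling. Of the 75 named genes that passed, 7 lost the call without 1 of the arrays, among them Cd74, Hamp, Kdr and Rpl19.

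**Figure D2:**
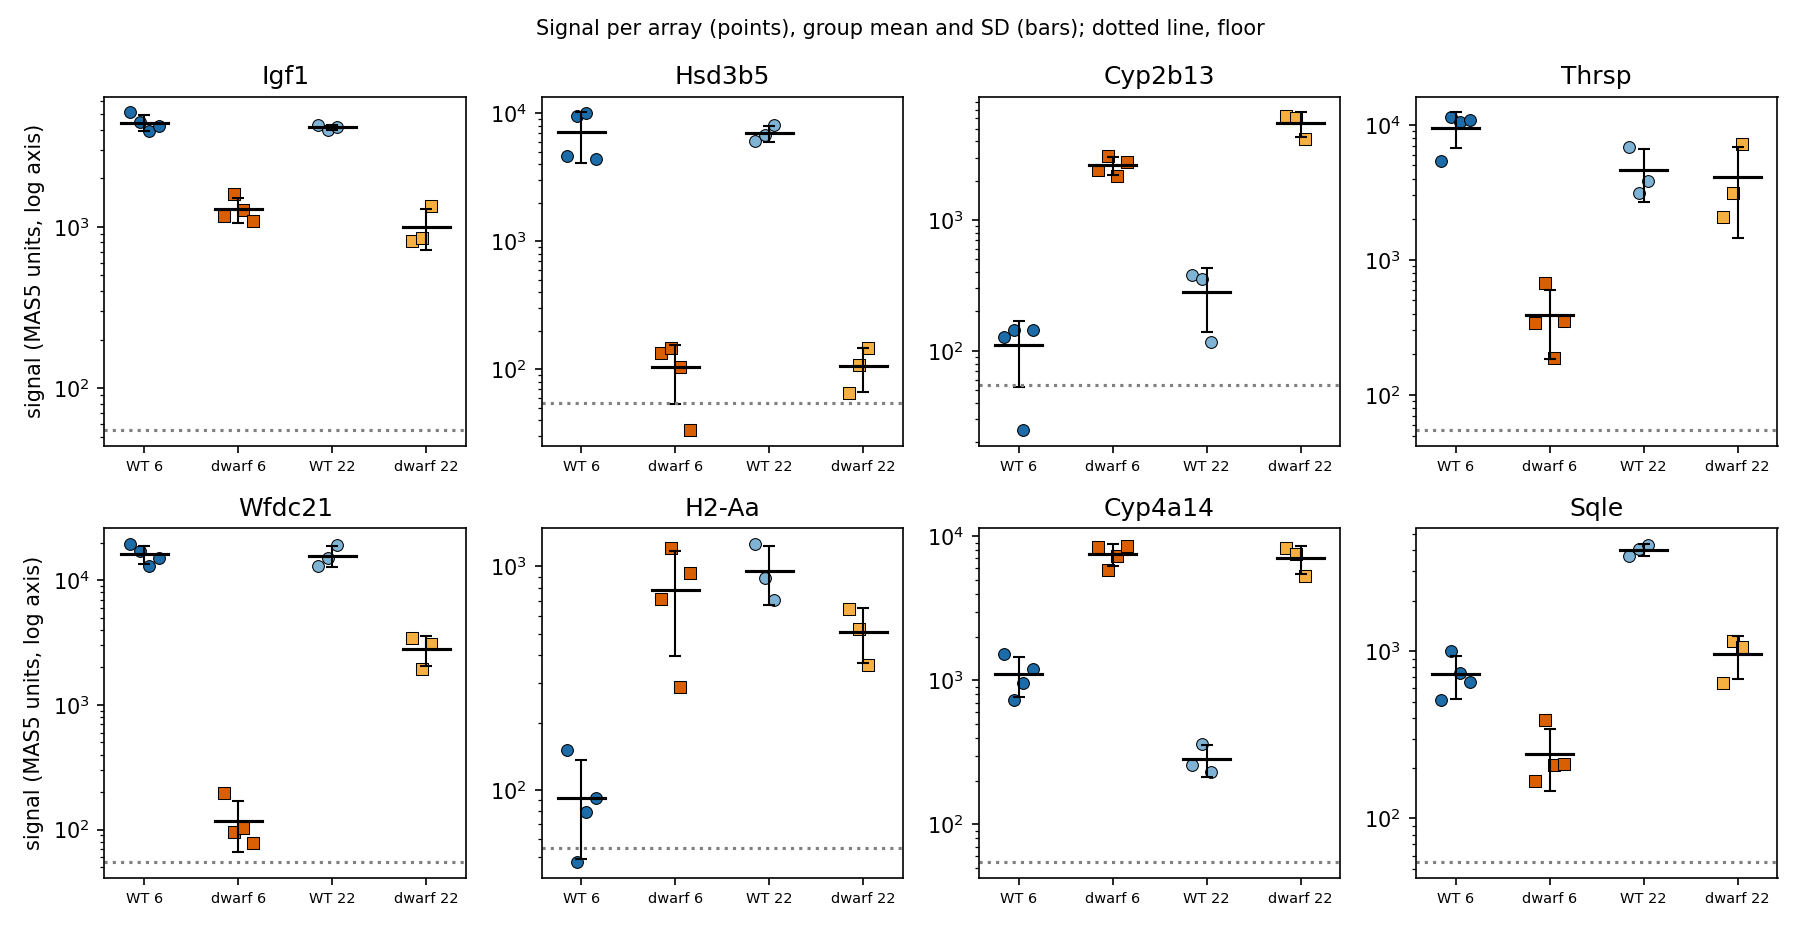
MAS5 signal (log axis) of 8 genes on each array, by group (WT, wild type; 6 and 22, age in months), with points for arrays, long bars for the group mean, whiskers for the SD (n = 4 at 6 months and 3 at 22 months) and a dotted line at the floor of 54.9. Igf1 and Hsd3b5 were lower and Cyp2b13 and Cyp4a14 higher in dwarf mice at both ages, while Thrsp was lower at 6 months and did not pass at 22 months.

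The comparison at 22 months asked which genotype differences are present in old mice (n = 3 and 3). Igf1 was 4.23-fold lower in dwarf mice (1005 ± 289 against 4144 ± 144), Igfals 8.81-fold lower and Socs2, a growth hormone-induced feedback inhibitor, 6.02-fold lower. Hsd3b5 was 68.5-fold lower, and Egfr was at least 20.7-fold lower, since all 3 dwarf arrays lay at the floor. Cyp4a14 and Cyp4a10, fatty acid omega-hydroxylases induced by PPAR-alpha, were 24.8-fold and 19.8-fold higher. In all, 99 probe sets were higher and 113 lower, 212 of 7227 (2.93%), and 61 and 84 of them differed by at least 2-fold. For these genes the limma adjusted p was 0.000217 or lower.

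Other large increases were in Sult2a2 (28-fold), Cyp2b13 (21.5-fold), Hao2 (20.2-fold), Pcp4l1 (15.5-fold), the annexin Anxa8 (7.55-fold) and Cyp2b9 (6.46-fold). Other large decreases were in Serpina12 (18.1-fold), Zap70, a kinase of T cell signalling (16-fold, 78.9 ± 33.5 against 1203 ± 134), Dct, dopachrome tautomerase (11-fold), the major urinary protein Mup5 (8.1-fold) and the secreted trefoil peptide Tff3 (6.74-fold). For these genes the adjusted p was 0.0155 or lower. The probe sets of Cyp4a10, Zap70 and Mup5 may also detect related transcripts.

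Genes of the growth hormone and IGF axis were lower as a list (adjusted p = 0.000123, or adjusted p = 0.0123 with an estimated correlation). Of 14 measured, 4 were lower and 10 did not pass (1 higher and 6 lower adjusted over the list alone). Male-biased liver genes were lower as a list (adjusted p = 4.21e-18, or adjusted p = 0.000569 with an estimated correlation). Of 9 measured, 6 were lower and 3 did not pass (7 lower adjusted over the list alone). Female-biased liver genes were higher as a list (adjusted p = 9.68e-17, or adjusted p = 0.00837 with an estimated correlation). Of 9 measured, 7 were higher and 2 did not pass (7 higher adjusted over the list alone). CAR and PXR regulated genes were higher as a list (adjusted p = 4.21e-18, or adjusted p = 0.000303 with an estimated correlation). Of 16 measured, 8 were higher and 8 did not pass (12 higher adjusted over the list alone). Nr1i3, which encodes CAR, was among them (1.66 ± 0.26). Cytochrome P450 2 family genes were higher as a list (adjusted p = 8.62e-05, or adjusted p = 0.016 with an estimated correlation). Of 13 measured, 5 were higher, 2 were lower and 6 did not pass (7 higher and 2 lower adjusted over the list alone). Cyp2c39 (2.10 ± 0.19) was higher and Cyp2f2 (-2.08 ± 0.27) lower. Genes of cytochrome P450 families 1, 3 and 4 were higher as a list (adjusted p = 4.81e-07, or adjusted p = 0.0106 with an estimated correlation). Of 10 measured, 5 were higher and 5 did not pass (6 higher and 1 lower adjusted over the list alone). Cyp3a11 (0.77 ± 0.14) and Cyp3a25 (1.05 ± 0.16) were higher. Glutathione transferases were higher as a list (adjusted p = 1.87e-08, or adjusted p = 0.027 with an estimated correlation). Of 16 measured, 7 were higher and 9 did not pass (8 higher and 1 lower adjusted over the list alone). Higher members were 2.47 ± 0.27 for Gsta2, 2.25 ± 0.41 for Gsta4, 1.84 ± 0.23 for Mgst3 and 1.70 ± 0.16 for Gstm3.

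PPAR-alpha targets were higher as a list (adjusted p = 1.74e-06, or adjusted p = 0.0188 with an estimated correlation). Of 14 measured, 4 were higher and 10 did not pass (6 higher adjusted over the list alone). Besides the Cyp4a genes these were 1.71 ± 0.23 for Acot1, an acyl-CoA thioesterase, and 1.54 ± 0.23 for Ehhadh, an enzyme of peroxisomal beta-oxidation. Mitochondrial fatty acid oxidation genes were higher as a list (adjusted p = 3.35e-06, or adjusted p = 0.0588 with an estimated correlation). Of 16 measured, 3 were higher and 13 did not pass (4 higher adjusted over the list alone). Acadm, the medium-chain acyl-CoA dehydrogenase, was higher (0.79 ± 0.13). Peroxisomal fatty acid oxidation genes were higher as a list (adjusted p = 0.00194, or adjusted p = 0.112 with an estimated correlation). Of 12 measured, 1 was higher and 11 did not pass (3 higher adjusted over the list alone). Amino acid catabolism genes were higher as a list (adjusted p = 1.26e-05, or adjusted p = 0.112 with an estimated correlation). Of 18 measured, 2 were higher and 16 did not pass (7 higher adjusted over the list alone). Cholesterol synthesis genes were lower as a list (adjusted p = 8.37e-07, or adjusted p = 0.0463 with an estimated correlation). Of 17 measured, 2 were lower and 15 did not pass (6 lower adjusted over the list alone). Sqle was lower (-2.12 ± 0.30). Fatty acid synthesis genes were lower as a list (adjusted p = 0.0243, or adjusted p = 0.449 with an estimated correlation). Of 13 measured, 1 was lower and 12 did not pass (2 lower adjusted over the list alone). Thrsp had -0.27 ± 0.46 (adjusted p = 0.93) and Me1 -0.90 ± 0.37 (adjusted p = 0.298). Among the lists of fuel use, higher calls came from glycolysis and glucose entry (1 higher of 7, 3 higher adjusted over the list alone, adjusted p = 0.0294, or adjusted p = 0.118 with an estimated correlation), glycogen metabolism (1 higher of 6, 1 higher adjusted over the list alone, adjusted p = 0.0107, or adjusted p = 0.0588 with an estimated correlation) and the tricarboxylic acid cycle (1 higher of 17, 1 higher adjusted over the list alone, adjusted p = 0.00194, or adjusted p = 0.167 with an estimated correlation). Idh2, a mitochondrial isocitrate dehydrogenase, was the tricarboxylic acid cycle gene called (1.75 ± 0.22). Other shifts upwards were those of oxidative phosphorylation (0 passed of 42, 0 passed adjusted over the list alone, adjusted p = 0.00187, or adjusted p = 0.347 with an estimated correlation), pericentral hepatocyte genes (0 passed of 9, 3 higher adjusted over the list alone, adjusted p = 0.00833, or adjusted p = 0.0864 with an estimated correlation) and metallothioneins (0 passed of 3, 2 higher adjusted over the list alone, adjusted p = 0.0107, or adjusted p = 0.0864 with an estimated correlation).

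Complement genes were lower as a list (adjusted p = 6.65e-11, or adjusted p = 0.00915 with an estimated correlation). Of 17 measured, 6 were lower and 11 did not pass (11 lower adjusted over the list alone). Examples were -1.57 ± 0.21 for C9, -1.09 ± 0.18 for Hc, -1.01 ± 0.15 for C1ra and -0.96 ± 0.17 for Serping1. Kupffer cell and macrophage markers were lower as a list (adjusted p = 2.29e-07, or adjusted p = 0.0463 with an estimated correlation). Of 17 measured, 3 were lower and 14 did not pass (8 lower adjusted over the list alone). Interferon-stimulated genes were lower as a list (adjusted p = 4.58e-07, or adjusted p = 0.0491 with an estimated correlation). Of 14 measured, 2 were lower and 12 did not pass (6 lower adjusted over the list alone). Ifi27 was lower (-1.34 ± 0.21). MHC class I and antigen processing genes were lower as a list (adjusted p = 9.13e-07, or adjusted p = 0.0635 with an estimated correlation). Of 13 measured, 1 was lower and 12 did not pass (7 lower adjusted over the list alone). Endoplasmic reticulum chaperones were lower as a list (adjusted p = 0.000967, or adjusted p = 0.0188 with an estimated correlation). Of 17 measured, 1 was lower and 16 did not pass (1 lower adjusted over the list alone). Xbp1, a transcription factor of the unfolded protein response, was lower (-1.03 ± 0.19). Acute phase proteins were lower as a list (adjusted p = 0.00194, or adjusted p = 0.206 with an estimated correlation). Of 21 measured, 2 were lower and 19 did not pass (5 lower adjusted over the list alone). Apcs was lower (-1.71 ± 0.27). Lower shifts with few single calls were those of coagulation and fibrinolysis (1 lower of 19, 5 lower adjusted over the list alone, adjusted p = 0.000206, or adjusted p = 0.0864 with an estimated correlation) and serine protease inhibitors (1 lower of 11, 1 lower adjusted over the list alone, adjusted p = 0.0313, or adjusted p = 0.112 with an estimated correlation) and of MHC class II genes (0 passed of 9, 0 passed adjusted over the list alone, adjusted p = 0.0448, or adjusted p = 0.339 with an estimated correlation) and cytosolic ribosomal proteins (1 lower of 20, 1 lower adjusted over the list alone, adjusted p = 0.034, or adjusted p = 0.447 with an estimated correlation). Without dwarf animal 3 the count of higher probe sets was 49 and without dwarf animal 4 it was 63, and with array weights the counts were 215 and 227. List calls ended under some settings (highest adjusted p of each list): without wild type animal 1, 0.462 for fatty acid synthesis and 0.0573 for metallothioneins; without dwarf animal 8, 0.0632 for glycolysis and glucose entry, 0.0859 for serine protease inhibitors and 0.227 for cytosolic ribosomal proteins; without a filter, 0.26 for MHC class II and antigen-presenting cells; with the filter at the 75th percentile, 0.0518 for pericentral hepatocyte genes. Of the 57 named genes that passed, 17 lost the call without 1 of the arrays, Tff3, Idi1 and Ugp2 among them.

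**Figure D3:**
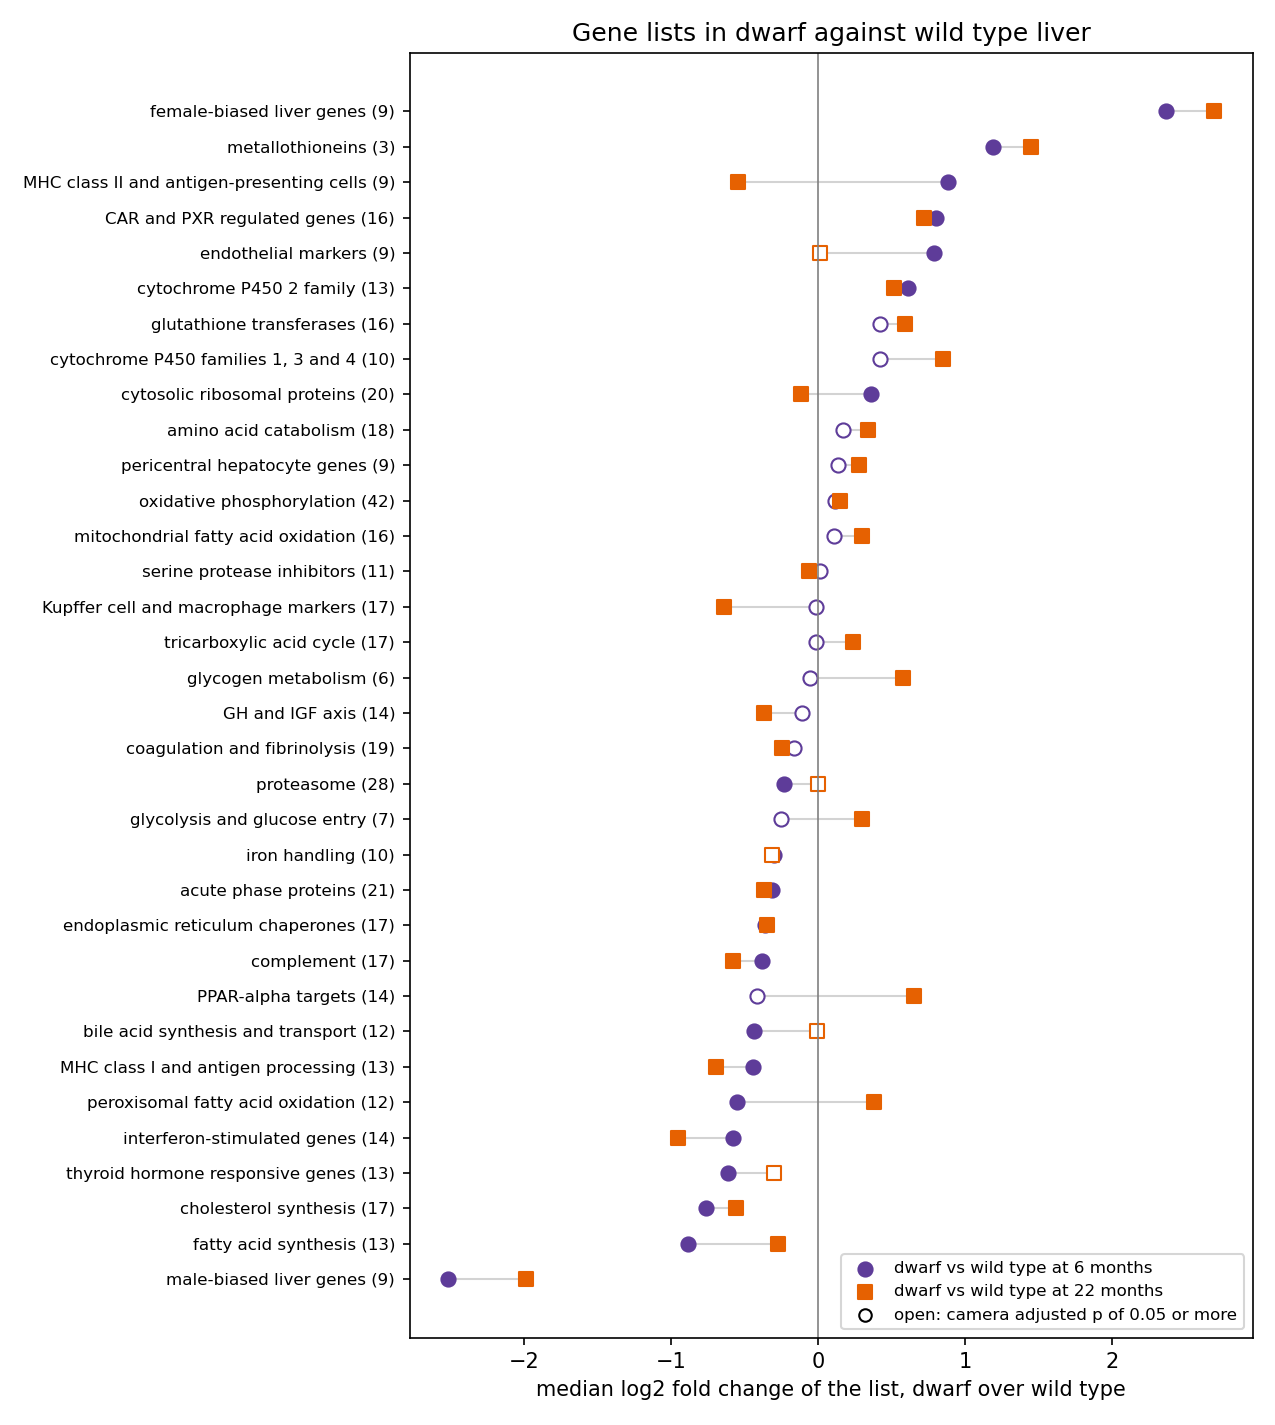
Median log2 fold change, dwarf over wild type, of each gene list that passed camera at 6 months (circles) or 22 months (squares), with the number of measured genes in brackets and open symbols for lists with an adjusted p of 0.05 or more. PPAR-alpha targets stood at -0.41 at 6 months, where they did not pass, and at 0.65 at 22 months.

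Across the 7227 tested probe sets, the genotype differences at 6 and 22 months had a Pearson r of 0.463 and a Spearman rho of 0.247, over genes, which are not independent replicates. Of the probe sets called at both ages, 44 were higher at both (6.3 by chance), 78 were lower at both (7.85 by chance) and 4 had opposite directions. Of the 212 calls at 22 months, 83.5% had the same sign at 6 months, and of the 962 calls at 6 months 71% had the same sign at 22 months. With the filter at the 75th percentile r was 0.601.

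Averaged over both ages, the genotype difference gave 336 higher and 406 lower probe sets, 742 of 7227 (10.3%). Igf1 was 3.83-fold lower and Igfals had a log2 change of -4.17 ± 0.23 and Socs2 -1.74 ± 0.22 (n = 7 and 7). Of the 24 lists that passed, 10 also passed with an estimated correlation, with adjusted p from 0.00168 to 0.0444 there and from 1.66e-15 to 0.00459 at the preset one (in brackets, members called and members called when adjusted over the list alone). Lower among these were male-biased liver genes (7 lower of 9, and 7 lower), complement (10 lower of 17, and 11 lower), cholesterol synthesis (10 lower of 17, and 11 lower), thyroid hormone responsive genes (6 lower of 13, and 6 lower), endoplasmic reticulum chaperones (8 lower of 17, and 1 higher and 11 lower) and GH and IGF axis (3 higher and 5 lower of 14, and 4 higher and 5 lower). Higher were female-biased liver genes (8 higher of 9, and 8 higher), CAR and PXR regulated genes (12 higher of 16, and 12 higher and 1 lower), cytochrome P450 2 family (7 higher and 2 lower of 13, and 8 higher and 2 lower) and cytochrome P450 families 1, 3 and 4 (6 higher and 1 lower of 10, and 7 higher and 1 lower). The remaining 14 lists that passed lost the call there, with adjusted p from 0.0625 to 0.324 with an estimated correlation. Of these, lower ones were fatty acid synthesis (9 lower of 13, and 1 higher and 11 lower), bile acid synthesis and transport (2 lower of 12, and 5 lower), MHC class I and antigen processing (8 lower of 13, and 10 lower), interferon-stimulated genes (1 higher and 6 lower of 14, and 1 higher and 8 lower), Kupffer cell and macrophage markers (3 lower of 17, and 5 lower), acute phase proteins (6 lower of 21, and 1 higher and 9 lower), coagulation and fibrinolysis (5 lower of 19, and 6 lower), iron handling (2 lower of 10, and 1 higher and 4 lower) and proteasome (1 lower of 28, and 1 lower). Higher ones were glutathione transferases (9 higher of 16, and 9 higher and 1 lower), metallothioneins (2 higher of 3, and 3 higher), amino acid catabolism (4 higher of 18, and 5 higher), mitochondrial fatty acid oxidation (3 higher of 16, and 3 higher) and endothelial markers (2 higher of 9, and 4 higher and 1 lower). Gsta2 (1.68 ± 0.18), Mt1 (1.67 ± 0.32) and Psmb8 (-1.14 ± 0.26) were examples. With median scaling 186 probe sets were higher and 25.5% of the calls were higher, against 45.3% as deposited. List calls ended under some settings (highest adjusted p of each list): without dwarf animal 3, 0.0649 for mitochondrial fatty acid oxidation; with the filter at the 75th percentile, 0.363 for endothelial markers and 0.0764 for proteasome. In all, 9 of the 75 named genes that passed lost the call without 1 of the arrays.

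The comparison of 22 with 6 months in wild type mice asked what ageing does in the control liver (n = 3 and 4). Tff3, a secreted trefoil peptide of mucosal surfaces, rose 58.9-fold (4430.3 ± 1921 against 71.2 ± 23.7), and the MHC class II chains H2-Aa and H2-Ab1 rose 10.5-fold and 4.2-fold. Sqle, squalene epoxidase, rose 5.71-fold, the immunoglobulin light chain segment Igkv6-23 7.12-fold and the tetraspanin Cd63 4.08-fold. The largest falls were in Fosl2 (at least 5.78-fold, since all 3 old arrays lay at the floor), the water channel Aqp4 (4.97-fold), Cyp4a10 (4.65-fold), Bpifa2 (4.15-fold), Adam28 (3.93-fold) and Cyp4a14 (3.81-fold). In all, 105 probe sets rose and 75 fell, 180 of 7227 (2.49%), each with limma adjusted p under the threshold.

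MHC class II and antigen-presenting cell genes rose as a list (adjusted p = 9.89e-06, or adjusted p = 0.125 with an estimated correlation). Of 9 measured, 4 rose and 5 did not pass (6 rose adjusted over the list alone). Cd74, the invariant chain, rose (1.20 ± 0.28). B cell and plasma cell markers rose as a list (adjusted p = 0.00241, or adjusted p = 0.125 with an estimated correlation). Of 9 measured, 3 rose and 6 did not pass (5 rose adjusted over the list alone). Ighm (1.01 ± 0.22) and Jchain (1.07 ± 0.24), which join in secreted IgM, rose. Kupffer cell and macrophage markers rose as a list (adjusted p = 0.00026, or adjusted p = 0.209 with an estimated correlation). Of 17 measured, 2 rose and 15 did not pass (6 rose adjusted over the list alone). Laptm5 rose (0.85 ± 0.13). MHC class I and antigen processing genes rose as a list (adjusted p = 0.001, or adjusted p = 0.254 with an estimated correlation). Of 13 measured, 2 rose and 11 did not pass (3 rose adjusted over the list alone). Psme1 rose (0.92 ± 0.17). Interferon-stimulated genes rose as a list (adjusted p = 0.000892, or adjusted p = 0.228 with an estimated correlation). Of 14 measured, 1 rose and 13 did not pass (3 rose adjusted over the list alone). Lysosomal proteases and hydrolases rose as a list (adjusted p = 7.78e-05, or adjusted p = 0.203 with an estimated correlation). Of 21 measured, 5 rose and 16 did not pass (7 rose adjusted over the list alone). Rises included 0.87 ± 0.15 for Ctsa, 0.92 ± 0.18 for Hexa and 0.87 ± 0.18 for Npc2. Cholesterol synthesis genes rose as a list (adjusted p = 1.32e-07, or adjusted p = 0.0766 with an estimated correlation). Of 17 measured, 4 rose and 13 did not pass (9 rose adjusted over the list alone). Besides Sqle these were 1.62 ± 0.22 for Dhcr7, 2.00 ± 0.45 for Mvd and 1.24 ± 0.26 for Lss. Coagulation and fibrinolysis genes rose as a list (adjusted p = 0.0064, or adjusted p = 0.254 with an estimated correlation). Of 19 measured, 3 rose and 16 did not pass (4 rose adjusted over the list alone). Pros1, protein S, rose (1.07 ± 0.18). Other lists that rose were endoplasmic reticulum chaperones (0 passed of 17, 3 rose adjusted over the list alone, adjusted p = 0.00241, or adjusted p = 0.0649 with an estimated correlation), cytosolic ribosomal proteins (1 rose of 20, 2 rose adjusted over the list alone, adjusted p = 0.00312, or adjusted p = 0.344 with an estimated correlation) and immediate early genes (1 rose of 12, 6 rose and 1 fell adjusted over the list alone, adjusted p = 0.0197, or adjusted p = 0.228 with an estimated correlation), with Btg2 at 1.90 ± 0.30.

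PPAR-alpha targets fell as a list (adjusted p = 1.32e-07, or adjusted p = 0.0631 with an estimated correlation). Of 14 measured, 3 fell and 11 did not pass (8 fell adjusted over the list alone). Acot1 fell besides the Cyp4a genes (-1.13 ± 0.21). Genes of cytochrome P450 families 1, 3 and 4 fell as a list (adjusted p = 3.59e-05, or adjusted p = 0.0649 with an estimated correlation). Of 10 measured, 4 fell and 6 did not pass (5 fell adjusted over the list alone). Peroxisomal fatty acid oxidation genes fell as a list (adjusted p = 0.00596, or adjusted p = 0.228 with an estimated correlation). Of 12 measured, 1 fell and 11 did not pass (1 rose and 6 fell adjusted over the list alone). Abcd3 fell (-0.89 ± 0.14). Mitochondrial fatty acid oxidation genes fell as a list (adjusted p = 0.0267, or adjusted p = 0.344 with an estimated correlation). Of 16 measured, 1 fell and 15 did not pass (1 rose and 4 fell adjusted over the list alone). Cpt2, a carnitine palmitoyltransferase, fell (-0.70 ± 0.14). Thyroid hormone responsive genes fell as a list (adjusted p = 0.0133, or adjusted p = 0.175 with an estimated correlation). Of 13 measured, 1 fell and 12 did not pass (3 fell adjusted over the list alone). Pck1, the gluconeogenic carboxykinase, fell (-0.99 ± 0.23). Other lists that fell were gluconeogenesis (1 fell of 9, 2 fell adjusted over the list alone, adjusted p = 0.0469, or adjusted p = 0.283 with an estimated correlation) and oxidative phosphorylation (1 fell of 42, 2 fell adjusted over the list alone, adjusted p = 0.0187, or adjusted p = 0.497 with an estimated correlation) and erythroid genes (0 passed of 5, 1 fell adjusted over the list alone, adjusted p = 0.0137, or adjusted p = 0.125 with an estimated correlation) and skeletal muscle genes (0 passed of 7, 0 passed adjusted over the list alone, adjusted p = 0.0469, or adjusted p = 0.283 with an estimated correlation). Of the growth hormone axis, Ghr, the receptor, fell (-0.61 ± 0.13), while Igf1 had -0.09 ± 0.18 (adjusted p = 0.832). Beside these lists, the mean log2 18S control signal was 9.99 at 22 months and 7.37 at 6 months (exact two-sided permutation p = 0.0857, or 0.245 adjusted over 20 tests), and with it as a covariate 7 and 2 probe sets passed. Without animal 88 the counts were 268 and 189, without 22-month animal 1 they were 32 and 28, without animal 2 38 and 31, without animal 24 49 and 19, without 6-month animal 84 40 and 25, without animal 86 42 and 19, and without animal 82 the falls were 47. List calls ended under some settings (highest adjusted p of each list): without wild type animal 88, 0.129 for thyroid hormone responsive genes, 0.136 for mitochondrial fatty acid oxidation and 0.208 for gluconeogenesis; without wild type animal 24, 0.0638 for peroxisomal fatty acid oxidation; with the filter at the 75th percentile, 0.186 for erythroid genes and 0.302 for immediate early genes; with the 18S signal as a covariate, 0.169 for skeletal muscle genes; with the 3'/5' ratio as a covariate, 0.151 for oxidative phosphorylation. Of the 41 named genes that passed, 27 lost the call without 1 of the arrays, and of those given here these were Fosl2, Adam28, Cyp4a10, H2-Ab1, Cd74, Ighm, Jchain, Psme1, Hexa, Npc2, Mvd, Lss, Acot1, Cpt2, Pck1 and Ghr. Cd74, Cpt2 and Ghr also lost it with median scaling.

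The comparison of 22 with 6 months in dwarf mice asked what ageing does without Pit-1 (n = 3 and 4). Wfdc21, Orm1, Thrsp and Igfals, which were low in young dwarf mice, rose with age: Wfdc21 24.7-fold (2819.8 ± 764 against 118 ± 52.7), Orm1 15.1-fold, Thrsp 10.2-fold (4133 ± 2688 against 389.8 ± 204) and Igfals, with a log2 change of 1.65 ± 0.32. Igf1 had -0.37 ± 0.18 (adjusted p = 0.153). Wfdc2 (11.9-fold), Anxa8 (7.9-fold, 3 of 4 young arrays at the floor) and Orm3 (7.83-fold) also rose. The largest falls were in Igfbp2 (5.43-fold, 4257 ± 3209 against 15412 ± 4132), Ercc1 (5.13-fold), Gsdme (5-fold), Rps13 (4.59-fold), Myf6 (4.47-fold) and Map3k12 (4.19-fold). Each lost the call with either covariate given below. Of named genes, Wfdc21, Orm1, Thrsp, Anxa8, Hsd17b4 and Sqle alone kept it with both. In all, 574 probe sets rose and 619 fell, 1193 of 7227 (16.5%) by limma.

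Fatty acid synthesis genes rose as a list (adjusted p = 5.83e-07, or adjusted p = 0.396 with an estimated correlation). Of 13 measured, 10 rose and 3 did not pass (12 rose and 1 fell adjusted over the list alone). Besides Thrsp these included 2.15 ± 0.35 for Me1, malic enzyme, 1.09 ± 0.23 for Elovl5 and 0.86 ± 0.15 for Slc25a1, the mitochondrial citrate carrier, and Fasn rose (2.06 ± 0.45). Cholesterol synthesis genes rose as a list (adjusted p = 1.5e-05, or adjusted p = 0.277 with an estimated correlation). Of 17 measured, 10 rose, 1 fell and 6 did not pass (11 rose and 1 fell adjusted over the list alone). Rises were 2.00 ± 0.28 for Sqle, 1.73 ± 0.27 for Msmo1, 1.52 ± 0.22 for Dhcr7 and 1.51 ± 0.22 for Hmgcs1. Peroxisomal fatty acid oxidation genes rose as a list (adjusted p = 0.0133, or adjusted p = 0.396 with an estimated correlation). Of 12 measured, 4 rose, 1 fell and 7 did not pass (4 rose and 1 fell adjusted over the list alone). Hsd17b4 (1.25 ± 0.16) and Ehhadh (1.24 ± 0.22) rose. Glycolysis and glucose entry genes rose as a list (adjusted p = 0.0403, or adjusted p = 0.396 with an estimated correlation). Of 7 measured, 3 rose and 4 did not pass (3 rose adjusted over the list alone). Pklr, the liver pyruvate kinase, rose (1.53 ± 0.24). NRF2 targets and antioxidant genes rose as a list (adjusted p = 0.0403, or adjusted p = 0.277 with an estimated correlation). Of 17 measured, 6 rose, 2 fell and 9 did not pass (7 rose and 3 fell adjusted over the list alone). Gsr, glutathione reductase, rose (0.88 ± 0.14) and Srxn1, sulfiredoxin, fell (-0.91 ± 0.21). Endoplasmic reticulum chaperones rose as a list (adjusted p = 0.032, or adjusted p = 0.277 with an estimated correlation). Of 17 measured, 4 rose, 1 fell and 12 did not pass (7 rose and 1 fell adjusted over the list alone). Pdia6 (1.74 ± 0.33) rose and Ddit3 fell (-0.85 ± 0.20). Proteasome genes rose as a list (adjusted p = 0.0167, or adjusted p = 0.621 with an estimated correlation). Of 28 measured, 6 rose, 1 fell and 21 did not pass (7 rose and 1 fell adjusted over the list alone). Lysosomal proteases and hydrolases rose as a list (adjusted p = 0.032, or adjusted p = 0.621 with an estimated correlation). Of 21 measured, 2 rose, 1 fell and 18 did not pass (2 rose and 1 fell adjusted over the list alone). Cytosolic ribosomal protein genes fell as a list (adjusted p = 0.0403, or adjusted p = 0.621 with an estimated correlation). Of 20 measured, 7 fell and 13 did not pass (1 rose and 9 fell adjusted over the list alone). Control transcripts moved beside all of these lists: in dwarf mice the mean log2 ratio of 3' to 5' signal was 0.19 at 22 months and 0.95 at 6 months, and the mean log2 18S signal was 9.18 and 6.79 (exact two-sided permutation p = 0.0286 for each, the smallest possible, or 0.114 adjusted over 20 tests). With the ratio as a covariate 38 probe sets passed as higher and 13 as lower, with the 18S signal 78 and 32, and with median scaling 925 and 242, so that 79.3% rather than 48.1% of the calls were rises and the median of all probe sets moved from -0.09 to 0.12. Without dwarf animal 3 of 22 months the counts were 290 and 231, without animal 4 354 and 308, without animal 8 344 and 388, and without 6-month dwarf animals 87 and 89 the falls were 334 and 406. List calls ended under some settings (highest adjusted p of each list): with quantile scaling, 0.0604 for peroxisomal fatty acid oxidation, 0.149 for proteasome, 0.135 for endoplasmic reticulum chaperones and 0.135 for lysosomal proteases and hydrolases; with the filter at the 75th percentile, 0.16 for glycolysis and glucose entry and 0.235 for NRF2 targets and antioxidants; with the 3'/5' ratio as a covariate, 0.649 for cytosolic ribosomal proteins. Of the 48 named genes that passed, 14 lost the call without 1 of the arrays, Map3k12, Srxn1 and Ddit3 among them. Ddit3 also lost it with median scaling, and 6 of the 48 kept it in all settings.

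Age changes in wild type and dwarf mice had a Pearson r of 0.415 and a Spearman rho of 0.41 (7227 probe sets). Of probe sets called in both genotypes, 37 rose (8.34 by chance), 27 fell (6.42 by chance) and 5 moved in opposite directions. Of 1193 dwarf calls 78% had the same sign in wild type mice, and of 180 wild type calls 73.9% in dwarf mice. A processing difference between the ages could give such agreement.

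The interaction asked whether the genotype difference changes with age, and a positive log2 value means that dwarf minus wild type was larger at 22 than at 6 months. Several of the genes that were lowest in young dwarf mice lost part of that deficit: the genotype difference in Wfdc21 was -7.18 ± 0.25 at 6 months and the interaction was 4.67 ± 0.38, Thrsp had 4.42 ± 0.61, Orm1 3.65 ± 0.64 and Me1 2.58 ± 0.50. Anxa8 (3.82 ± 0.56), Aqp4 (3.37 ± 0.55) and Wfdc2 (3.37 ± 0.70) also increased. In the other direction, H2-Aa had -3.88 ± 0.59: its mean signal went from 92.3 ± 43.1 to 950.2 ± 279.7 in wild type mice and from 786 ± 389 to 509.6 ± 140.2 in dwarf mice. Decreases were also called in Tff3 (-3.82 ± 0.79), Igfbp2 (-3.55 ± 0.87), Ahnak (-2.80 ± 0.56), Il1rn (-2.78 ± 0.63) and Cd63 (-2.63 ± 0.51). In all, the difference increased in 111 and decreased in 47 of 7227 probe sets (2.19%, limma, n = 4, 4, 3 and 3).

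In the counts that follow, increased and decreased refer to the genotype difference. PPAR-alpha targets increased as a list (adjusted p = 9.27e-09, or adjusted p = 0.0361 with an estimated correlation). Of 14 measured, 5 increased and 9 did not pass (9 increased adjusted over the list alone). Increases were 2.22 ± 0.30 for Acot1, 1.96 ± 0.31 for Ehhadh, 1.83 ± 0.34 for Cyp4a14 and 1.82 ± 0.38 for Acaa1b. Peroxisomal fatty acid oxidation genes increased as a list (adjusted p = 1.1e-06, or adjusted p = 0.0955 with an estimated correlation). Of 12 measured, 4 increased and 8 did not pass (7 increased adjusted over the list alone). Hsd17b4 (1.59 ± 0.23) and Abcd3 (1.19 ± 0.20) increased. Fatty acid synthesis genes increased as a list (adjusted p = 1.28e-06, or adjusted p = 0.167 with an estimated correlation). Of 13 measured, 3 increased and 10 did not pass (8 increased adjusted over the list alone). Elovl5 increased besides Thrsp and Me1 (1.57 ± 0.32). Mitochondrial fatty acid oxidation genes increased as a list (adjusted p = 0.000973, or adjusted p = 0.167 with an estimated correlation). Of 16 measured, 2 increased and 14 did not pass (5 increased adjusted over the list alone). Thyroid hormone responsive genes increased as a list (adjusted p = 0.00578, or adjusted p = 0.114 with an estimated correlation). Of 13 measured, 2 increased and 11 did not pass (3 increased adjusted over the list alone). Glycolysis and glucose entry genes increased as a list (adjusted p = 0.00377, or adjusted p = 0.114 with an estimated correlation). Of 7 measured, 3 increased and 4 did not pass (3 increased adjusted over the list alone). Pklr increased (1.59 ± 0.34). MHC class II and antigen-presenting cell genes decreased as a list (adjusted p = 2.02e-05, or adjusted p = 0.114 with an estimated correlation). Of 9 measured, 3 decreased and 6 did not pass (6 decreased adjusted over the list alone). H2-Eb1 decreased (-1.43 ± 0.31). Kupffer cell and macrophage markers decreased as a list (adjusted p = 2.56e-05, or adjusted p = 0.128 with an estimated correlation). Of 17 measured, 2 decreased and 15 did not pass (4 decreased adjusted over the list alone). Aif1 (-1.76 ± 0.37) and Laptm5 (-0.95 ± 0.19) decreased. Cytosolic ribosomal protein genes decreased as a list (adjusted p = 1.22e-06, or adjusted p = 0.139 with an estimated correlation). Of 20 measured, 0 passed singly (8 decreased adjusted over the list alone). B cell and plasma cell markers decreased as a list (adjusted p = 0.00578, or adjusted p = 0.135 with an estimated correlation). Of 9 measured, 1 decreased and 8 did not pass (3 decreased adjusted over the list alone). Erythroid genes increased as a list (adjusted p = 0.00259, or adjusted p = 0.0955 with an estimated correlation). Of 5 measured, 1 increased and 4 did not pass (1 increased adjusted over the list alone). Alas2 increased (1.89 ± 0.31).

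Further lists with an increase were CAR and PXR regulated genes (4 increased of 16, 4 increased adjusted over the list alone, adjusted p = 0.00271, or adjusted p = 0.109 with an estimated correlation), the tricarboxylic acid cycle (2 increased of 17, 2 increased adjusted over the list alone, adjusted p = 0.00227, or adjusted p = 0.179 with an estimated correlation) and cytochrome P450 families 1, 3 and 4 (2 increased of 10, 3 increased adjusted over the list alone, adjusted p = 0.00351, or adjusted p = 0.114 with an estimated correlation), with Dlst at 1.29 ± 0.23 and Cyp3a25 at 1.12 ± 0.21. Others on detoxification and protein turnover were glutathione transferases (2 increased of 16, 3 increased adjusted over the list alone, adjusted p = 0.005, or adjusted p = 0.212 with an estimated correlation), NRF2 targets and antioxidants (1 increased of 17, 4 increased and 1 decreased adjusted over the list alone, adjusted p = 0.0269, or adjusted p = 0.114 with an estimated correlation) and the proteasome (0 passed of 28, 0 passed adjusted over the list alone, adjusted p = 0.00154, or adjusted p = 0.212 with an estimated correlation), with Ephx1, microsomal epoxide hydrolase, at 1.37 ± 0.26. Metabolic lists with an increase were bile acid synthesis and transport (1 increased of 12, 1 increased adjusted over the list alone, adjusted p = 0.0133, or adjusted p = 0.139 with an estimated correlation) and amino acid catabolism (2 increased of 18, 2 increased adjusted over the list alone, adjusted p = 0.0315, or adjusted p = 0.449 with an estimated correlation), with Gldc, glycine decarboxylase, at 1.59 ± 0.39. Further decreases were those of immediate early genes (1 decreased of 12, 3 decreased adjusted over the list alone, adjusted p = 0.0269, or adjusted p = 0.179 with an estimated correlation), endothelial markers (0 passed of 9, 2 decreased adjusted over the list alone, adjusted p = 0.0385, or adjusted p = 0.167 with an estimated correlation) and sterol-regulated genes outside the synthesis pathway (0 passed of 6, 0 passed adjusted over the list alone, adjusted p = 0.0372, or adjusted p = 0.139 with an estimated correlation), with Btg2 at -2.51 ± 0.43. Igfals increased (2.05 ± 0.45) as did Ghr (0.88 ± 0.18), while Igf1 had -0.28 ± 0.25 (adjusted p = 0.659). Without dwarf animal 3 the counts were 36 and 12, without dwarf animals 4 and 8 64 and 24 and 49 and 20, without wild type animals 1 and 24 64 and 21 and 41 and 16, without wild type animal 82 the increases were 66, and without dwarf animals 87 and 89 the decreases were 28 and 26. With median scaling 89.7% rather than 70.3% of the calls were increases (156 and 18) and the median of all probe sets moved from -0.07 to 0.13, and counts were also over 1.5 times lower without a filter (51 and 18), without the intensity trend (44 and 20) and with the 3' to 5' ratio as a covariate (46 and 11). List calls ended under some settings (highest adjusted p of each list): without wild type animal 1, 0.144 for sterol-regulated genes outside the synthesis pathway; with quantile scaling, 0.0813 for bile acid synthesis and transport; without dwarf animal 3, 0.18 for amino acid catabolism; with the filter at the 75th percentile, 0.171 for NRF2 targets and antioxidants, 0.0502 for B cell and plasma cell markers and 0.171 for immediate early genes; with the 3'/5' ratio as a covariate, 0.282 for endothelial markers. Of the 44 named genes that passed, 30 lost the call without 1 of the arrays. Those given here that kept it without each array were Wfdc21, Thrsp, Orm1, Anxa8, Aqp4, H2-Aa, Acot1, Ehhadh, Hsd17b4, Abcd3, Alas2, Dlst and Btg2. H2-Eb1, Igfbp2 and Laptm5 also lost it with median scaling.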

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

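The tests of RNA quality and of the 18S signal on the age differences, of the age label of animal 88, of female mice in the dwarf groups and of a fasted state were chosen only after the result was seen. The bounds for the tests on the age differences were made stricter after their values were seen. The 3' to 5' ratio fits, also used for fatty acid synthesis, were added after seeing the data.

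Other splits of the arrays were fitted alike. At 6 months (962 calls, next 7) and for age in dwarf mice (1193, next 753) the real split of 35 alone gave as many. So did the real one of 100 assignments of genotype within each age for the average (742, next 196). This argues against chance, with shares unadjusted over contrasts. For the interaction the real one alone gave as many (158 and 64). Chance stays open there, because these assignments leave the genotype difference in the residuals. At 22 months the 10 splits are too few for a share under 0.05 (212 calls, and 0 for the highest other). For age in wild type mice 2 of 35 splits gave as many, so chance cannot be excluded: the real split gave 180 calls, and the split that puts the 6-month animal 88 with the 3 arrays of 22 months gave 322, which points to a structure of the samples. The 753 in dwarf mice came from joining 6-month animal 83 likewise.

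Age differences were called for 1193 probe sets in dwarf and 180 in wild type mice, while control transcripts moved with age and the 6-month animal 88 stood near the 22-month arrays. Against a wrong age label on animal 88, its mean was nearer the 6-month mean on 14 of 15 lists that pass with age in wild type mice without it, with oxidative phosphorylation as the exception. With the 3' to 5' ratio as a covariate the median share of the log2 change kept was 0.84 in dwarf mice (lower quartile 0.619, median standard error from 0.214 to 0.303, 44 of 1193 calls kept) and 0.985 in wild type mice (113 of 180 kept). With the 18S signal it was 0.878 in dwarf mice (108 kept) and 0.929 in wild type mice (9 kept, median standard error from 0.192 to 0.251). Ageing, RNA quality and a processing difference between the ages cannot be told apart, because the 18S signal nearly separates the ages and, on 75.7% of the 1193 probe sets, animal 88 lay toward the side of the 22-month dwarf arrays (28.3% to 48% for the other 6-month wild type arrays).

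Of 9 male-biased liver genes 7 were lower in dwarf mice at 6 months and 6 at 22 months, and of 9 female-biased ones 7 were higher at each age (at 6 months that list had an adjusted p of 0.062 with an estimated correlation). Female mice in the dwarf groups are argued against by the Y-linked Eif2s3y, whose dwarf over wild type ratio of mean signal was 0.901 at 6 months and 0.868 at 22 months with 307.9 as the lowest signal on any array, and by Xist, which reached at most 23, under the floor of 54.9. Scaling between arrays is argued against because 14 of 14 called genes at 6 months and 12 of 13 at 22 months (92.3%) kept call and direction under quantile and under median scaling. The loss of growth hormone in dwarf mice stays open, untested. The probe set of Eif2s3y may also detect related transcripts, and its mean signal in wild type mice was 447.4 at 6 months and 1040.2 at 22 months.

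Of 13 fatty acid synthesis genes 10 were lower in 6-month dwarf mice (adjusted p of the list 0.101 with an estimated correlation). RNA quality is argued against, since the called members kept a median share of 0.994 of the change with the 3' to 5' ratio as a covariate (9 of 10 calls kept). A single array is argued against, since the highest adjusted p of the list (preset correlation) with each 6-month array left out was 9.08e-09. A fasted state of the dwarf mice stays open, since PPAR-alpha targets had an adjusted p of 0.15 and so passed in neither direction. The lack of thyroid hormone and of growth hormone in dwarf mice also stays open, since the design does not separate them.

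Some 6-month arrays lay apart from the other 3 of their group by at least 0.838 of its range, however small. The median signal of animal 84 was 183.2, against 174.85 to 176.1 in the rest of its group. Of 532 named-gene and group pairs, 31 (5.83%) had such an array, where chance gives about 1 in 20, and 8 of the 31 came from animal 88. Log2 signals follow. Animal 82 had Ctss 10.52, Flt1 7.53, Gucy2c 6.55, Psmb10 9.94 and Thrsp 12.39. Animal 83 had Abcd2 9.60, Ctsd 11.66, Gbe1 7.47, Myh4 7.73, Serpinf2 12.65 and Vtn 13.53. Animal 84 had Cyp3a11 14.23 (rest 14.13 to 14.14). Animal 85 had Anxa8 7.31, Dio1 5.98, Igfbp2 13.18, Mpeg1 9.92 and Sucla2 10.48. Animal 86 had Cyp2b13 5.78. Animal 87 had Cd74 10.69, Eci1 11.17 and Idi1 8.07. Animal 88 had Adam28 7.57, Alas2 12, G6pc 11.79, Nr1i3 12.11, Pdia3 9.35, Pgm1 13.01, Proc 12.93 and Srebf1 13.14. Animal 89 had Clec4f 10.09 and Gldc 9.05.

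The genotype difference changed, by the interaction test, for 44 named genes: 30 lost the call without 1 array, 12 kept it in all settings. The log2 difference increased for Wfdc21 4.67, Thrsp 4.42, Anxa8 3.82, Orm1 3.65, Aqp4 3.37, Wfdc2 3.37, Me1 2.58, Acot1 2.22, Igfals 2.05, Ehhadh 1.96, Alas2 1.89, Aldh1a7 1.86, Cyp4a14 1.83, Acaa1b 1.82, Gldc 1.59, Pklr 1.59, Hsd17b4 1.59, Gsta2 1.58, Elovl5 1.57, Ephx1 1.37, Dlst 1.29, Bhmt 1.19, Abcd3 1.19, Cyp3a25 1.12, Slc25a20 1.09, Aldh1a1 0.95, Cpt2 0.92, Pgam1 0.90, Gstm3 0.90, Sdha 0.89, Ghr 0.88 and Pgk1 0.85. It decreased for H2-Aa -3.88, Tff3 -3.82, Igfbp2 -3.55, Ahnak -2.80, Il1rn -2.78, Cd63 -2.63, Btg2 -2.51, Aif1 -1.76, Cd74 -1.74, H2-Eb1 -1.43, Ighm -1.36 and Laptm5 -0.95. It also changed for 22 lists, with adjusted p of 9.27e-09 for PPAR-alpha targets, 1.1e-06 for peroxisomal fatty acid oxidation, 1.22e-06 for cytosolic ribosomal proteins, 1.28e-06 for fatty acid synthesis, 2.02e-05 for MHC class II and antigen-presenting cells, 2.56e-05 for Kupffer cell and macrophage markers, 0.000973 for mitochondrial fatty acid oxidation, 0.00154 for proteasome, 0.00227 for tricarboxylic acid cycle, 0.00259 for erythroid genes, 0.00271 for CAR and PXR regulated genes, 0.00351 for cytochrome P450 families 1, 3 and 4, 0.00377 for glycolysis and glucose entry, 0.005 for glutathione transferases, 0.00578 for thyroid hormone responsive genes, 0.00578 for B cell and plasma cell markers, 0.0133 for bile acid synthesis and transport, 0.0269 for NRF2 targets and antioxidants, 0.0269 for immediate early genes, 0.0315 for amino acid catabolism, 0.0372 for sterol-regulated genes outside the synthesis pathway and 0.0385 for endothelial markers, of which PPAR-alpha targets alone passed with an estimated correlation.

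A signal outside the main measurement was that of the 18S control, with 339.8 as the lowest and 542.6 as the median on the 22-month arrays, against 60.8 to 217.4 on the 6-month arrays other than animal 88 (587.6).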

How the results depend on the processing

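The covariate fits were chosen only after the result was seen. No call of a result reported here was reversed in direction under the alternatives given here, which leave out the dropped batch term. Of all 1193 dwarf age calls, 99.6% kept their sign with the 3' to 5' ratio as a covariate. No paired analysis was run, since the labels name no pairs. Counts over 1.5 times from the main count, and other values that moved, follow; the cause was not tested, except that filters change the number of probe sets tested.

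With median scaling, values were 188 higher and 846 lower for 6 months, 63 higher and 43 lower for age in wild type, 925 higher and 242 lower for age in dwarf, 18 lower for the interaction and 186 higher for the average. With the compared groups alone, values were 279 higher for 6 months and 54 higher and 22 lower for age in wild type. With array weights, values were 215 higher and 227 lower for 22 months and 270 higher and 202 lower for age in wild type. Without a filter, values were 58 higher and 44 lower for age in wild type and 51 higher and 18 lower for the interaction. Without the intensity trend, values were 57 higher and 33 lower for age in wild type and 44 higher and 20 lower for the interaction. With the 18S signal as a covariate, values were 7 higher and 2 lower for age in wild type and 78 higher and 32 lower for age in dwarf. With the 3' to 5' ratio as a covariate, values were 47 lower for age in wild type, 38 higher and 13 lower for age in dwarf and 46 higher and 11 lower for the interaction. With an estimated correlation, values were 1 list for 6 months, 13 lists for 22 months, 0 lists for age in wild type, 0 lists for age in dwarf, 1 list for the interaction and 10 lists for the average. With fry, values were 34 lists for 6 months and 17 lists for age in dwarf. With mixed fry, values were 51 lists for 6 months, 39 lists for age in wild type, 45 lists for age in dwarf and 49 lists for the average. With quantile scaling, values were 3 lists for age in dwarf. With the filter at the 75th percentile, values were 4 lists for age in dwarf and r of the genotype differences 0.601.

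With each array left out in turn, the counts ranged over 322 to 508 higher and 384 to 590 lower for 6 months, 49 to 91 higher and 78 to 93 lower for 22 months, 32 to 268 higher and 19 to 189 lower for age in wild type, 290 to 695 higher and 231 to 756 lower for age in dwarf, 36 to 117 higher and 12 to 52 lower for the interaction and 225 to 378 higher and 310 to 455 lower for the average. The lists passing ranged over 19 to 22 for 6 months, 25 to 30 for 22 months, 15 to 24 for age in wild type, 5 to 10 for age in dwarf, 19 to 23 for the interaction and 23 to 26 for the average. Pearson r ranged from 0.408 to 0.471 for the genotype differences and from 0.356 to 0.466 for the ageing changes. The dwarf age lists were 5 without animal 8, and the other arrays that moved a count by over 1.5 times are named beside each comparison. Named genes kept their side of the threshold in 4459 fits, lost the call in 451 and gained it in 73; lists kept it in 1102 and lost it in 79. With an estimated correlation 99 of 124 list calls were lost.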

Other observations

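The tests on subsets of arrays were chosen only after the result was seen. Of the 57 lists, 15 passed in none of the 6 contrasts at the preset correlation. The lowest adjusted p over the contrasts was 0.0535 for stellate cell and matrix genes, 0.0774 for adipocyte genes, 0.0976 for heat shock and cytosolic chaperones, 0.0992 for T and NK cell markers, 0.169 for cell cycle genes, 0.17 for circadian clock genes, 0.171 for FoxO and insulin-regulated genes, 0.18 for apolipoproteins and lipoprotein handling, 0.186 for urea cycle and nitrogen, 0.214 for neutrophil markers, 0.237 for pancreatic acinar genes, 0.271 for triglyceride synthesis and lipid droplets, 0.292 for p53 targets and cell cycle inhibitors, 0.328 for periportal hepatocyte genes and 0.538 for UDP-glucuronosyl and sulfotransferases. Lists for major urinary proteins, ketone body metabolism and cholangiocyte markers had under 3 tested genes and were not tested.

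A probe set that the annotation does not list, with the largest genotype difference of the unlisted ones, had a genotype difference of 5.58 ± 0.25 at 6 months and 5.62 ± 0.29 at 22 months (log2, with the limma standard error), and it was chosen after its values were seen. With 3 of the 4 arrays per group at 6 months, the 16 subsets gave a median of 691.5 calls (573 to 1008), against 212 calls at 22 months. Eif2s3x, the X-linked homologue of Eif2s3y, had mean signals of 2558.1 in wild type and 2240.5 in dwarf mice of 6 months, and 2440.2 and 2336 at 22 months.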
